A study of Manihot esculenta with 4 samples.

How the data were processed

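Leaf RNA of cassava, Manihot esculenta, was measured by RNA sequencing in 4 libraries, all run on an Illumina HiSeq instrument per the labels. The libraries came from 2 cultivars, KU50 and Xinxuan048, each with 1 library from plants under normal conditions and 1 from plants under drought stress. The labels were used for every group, and the labels gave no duration or severity of the drought and no number of plants per library. Each group held 1 library, so no value has a replicate check within its own group.

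The values were FPKM, fragments scaled by transcript length and by the number of mapped fragments, which the authors deposited as 1 value per gene and library. The submitters' processing notes name TopHat2 2.0.12, a spliced aligner, and Cufflinks, which assembles and quantifies transcripts, with no role, order or settings. The Cufflinks version, the genome build and the annotation were not given in the sources used here. Each gene carried a MANES locus tag and the position of its locus. Positions are given as the deposited files give them, counted from 1. Loci spanned 150 to 63652 bases with a median of 3102, and 1 locus whose position was damaged in 1 library took its position from another library. The chromosome number was read from the tag, since each numbered tag prefix fell on 1 sequence of the files. The remaining tags lay on 363 unplaced sequences.

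The tags were looked up in a table of 34312 RefSeq cassava genes, and 0 of 27146 matched. The files do not pair tags with names or descriptions. The 35 gene lists fixed before the data were examined, which select genes by description, were therefore not applied, and markers of other cell types were not examined. The rule for named genes was also fixed before the data were examined. It took the shared drought effect from genes past the test and at least 2-fold in the same direction in both cultivars, by mean change, filled up with genes at least 2-fold in both and given as values only. For the other comparisons it took the highest and lowest log2 ratios among genes with at least 5 FPKM in at least 1 of the libraries compared. Its requirement of a description could not be met, so at most 2 tags in each direction of each comparison are printed, in the order of the same ranking. Genes named outside this rule are marked as chosen after their values were seen.

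No gene was listed with a value of 0. A gene absent from 1 library's file was taken as 0 FPKM there, and is called unlisted; 22869 genes were listed in all 4 libraries. For a gene unlisted in a library, values are printed instead of a fold. Genes with a mean of at least 1 FPKM over the 4 libraries were kept, 19743 in all. Values were analysed as log2(FPKM + 1), and every log2 ratio is on that scale, which understates differences of low genes. The FPKM as deposited were not rescaled in the main analysis.

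The drought effect shared by both cultivars and the cultivar effect shared by both conditions were tested with limma 3.58.1 in R 4.3.3, with moderated variances following a trend on mean expression. The fit used all 4 libraries, with cultivar and drought as additive terms. P-values were two-sided and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. This fit has 1 residual degree of freedom. The error of a gene combines the difference between its responses in the 2 cultivars with a variance estimated across genes of like mean, at 2.99 degrees of freedom. A p-value therefore sets the size of 2 single responses against that combined error. It does not measure the spread between plants of 1 group. No comparison within a cultivar or within a condition, and no difference of responses, has a test; for these, genes at least 2-fold apart were counted.

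The fit was tested on simulated data for the shared drought effect, with 19743 genes and 50 changed genes per size in each of 5 simulations. At the adjusted threshold it recovered 0.4% of genes changed by a log2 of 1, 41.6% at 2, 68% at 3 and 77.2% at 4. False calls numbered 4.8 per simulation on average, beside the recovered genes. Without adjustment, 5.19% of the unchanged simulated genes passed the same threshold. In the data 7457 of 19743 genes passed it, and the median drought log2 ratios were 0.30 in KU50 and 0.37 in Xinxuan048. The simulated recovery and false calls therefore do not carry over to the genes called in the data. Pearson's correlation across genes compared the 2 drought responses, which share no library. Genes are not independent replicates, so it has no p-value. Counts of neighbouring genes were set against 10000 random placements of as many genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

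The absolute number of fragments is unknown. At the shortest loci the values were whole multiples of 51.6 FPKM in KU50 control and of 54.5 in Xinxuan048 drought, taken as the worth of 1 fragment. In Xinxuan048 control the listed loci all had 60.2 FPKM, so no step was seen there. Taking 60.2 as the worth of 1 fragment is an assumption. These values rest on 4 loci, 3 of 150 bases and MANES_S072600. That locus spans 362 bases but had the same values as a locus of 150 bases in 2 libraries. In KU50 drought only 1 of them was listed, at 93.6 FPKM, so the worth of 1 fragment is not known there. Among genes below 0.3 FPKM in both libraries compared, the most frequent ratio to KU50 control gave relative depths of 0.973 for KU50 drought, 0.993 for Xinxuan048 control and 0.847 for Xinxuan048 drought. The values taken as 1 fragment at the shortest loci gave other ratios to KU50 control, 0.857 for Xinxuan048 control and 0.947 for Xinxuan048 drought. The 2 estimates were not reconciled, so relative depth is uncertain. A high FPKM at a very short locus can rest on a single fragment.

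The alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, upper-quartile scaling, scaling to a common total, scaling by trimmed means of log ratios (TMM, trimming 30% of ratios and 5% of means, without count weights) and a 4-fold threshold. For the tests they also included fits without the second term, without the variance trend and with an adjusted p threshold of 0.10, and for the correlation Spearman's rank correlation. The common total lay above every deposited total, so that scaling also made the pseudocount smaller relative to the values. Added after the data were seen were a restriction to genes listed in all 4 libraries, a restriction to loci of at least 500 bases, and the removal of genes with a mean of at least 300 FPKM followed by rescaling.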

Results

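Cassava is a root crop of the tropics, and KU50 and Xinxuan048 are cultivars of it. Leaves were sequenced from each cultivar under normal conditions and under drought, with 1 library per group. The title and design of the series place the question in the leaf's transcriptional response to drought. The number of genes listed was 25296 in KU50 control, 25336 in KU50 drought, 24405 in Xinxuan048 control and 25009 in Xinxuan048 drought. FPKM totals lay between 611226 and 636034. The median listed value was 5.95 FPKM in KU50 control and 7.63 in KU50 drought, and 5.33 and 7.24 in the same order in Xinxuan048. Genes are given by their locus tags, and the build behind their positions was not given in the sources used here.

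Some genes rose far under drought in both cultivars, and only a few of these passed the test. Those with the largest shared log2 effects among genes that passed the test, MANES_09G025200 and MANES_03G208800, were near silent in control leaves. MANES_09G025200, on chromosome 9 from 3779466 to 3789354, had 0.721 FPKM in KU50 control and 177 in KU50 drought. In Xinxuan048 the same gene had 0.345 FPKM in control and 101 in drought. Its shared log2 effect was 6.47 ± 0.18 (SE, 4 libraries; limma adjusted p = 0.0371). MANES_03G208800, on chromosome 3 from 28896616 to 28898137, had 1.25 and 102 FPKM in KU50 and 0.567 and 64.9 in Xinxuan048, control before drought. Its shared log2 effect was 5.46 ± 0.15 (SE; limma adjusted p = 0.0371). MANES_03G039900, on chromosome 3 from 3239470 to 3240390, fell from 90.5 to 5.30 FPKM in KU50 and from 143 to 8.16 in Xinxuan048. Its shared log2 effect was -3.92 ± 0.14 (SE; limma adjusted p = 0.0401).

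In all, 9 of 19743 genes passed the limma test at an adjusted p of 0.05, 8 of them higher and 1 lower under drought. All 9 were at least 2-fold apart in both cultivars, and the 8 that rose had shared log2 effects from 3.56 to 6.47. Large shared rises were not confined to these 8. MANES_03G197100, at least 2-fold higher in both cultivars, had a mean log2 ratio of 5.48, above that of MANES_03G208800, but missed the test (limma adjusted p = 0.0632). Among genes at least 2-fold lower in both cultivars, MANES_09G145900 on chromosome 9 had a lower mean log2 ratio than MANES_03G039900 but missed the test. It had 58.1 FPKM in KU50 control, 0.798 in KU50 drought, 25.2 in Xinxuan048 control and 1.92 in Xinxuan048 drought (limma adjusted p = 0.0632). At an unadjusted p of 0.05, 7457 genes passed, 6198 higher and 1259 lower. That split is for the FPKM as deposited, where most genes were higher under drought. By the same limma threshold, 5388 genes passed with upper-quartile scaling, 5249 with TMM and 8114 with totals scaled to a common value. The count of 9 is a feature of this threshold and scale: a filter at a mean of 5 FPKM gave 750 genes, no filter gave 0, and TMM scaling gave 378, of which 147 were higher and 231 lower. The 9 genes were among the calls under the stricter filter and under each of the 3 other scalings.

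**Figure D1:**
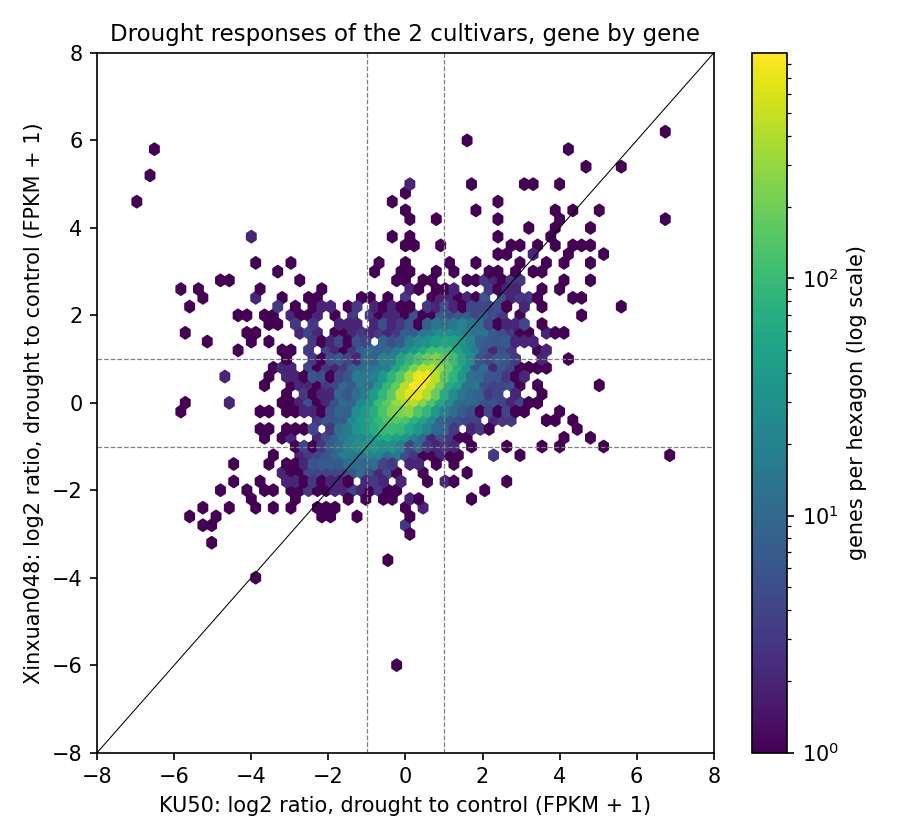
Each hexagon counts genes by their log2 ratio of drought to control in KU50 (horizontal) and Xinxuan048 (vertical), on log2(FPKM + 1), with dashed lines at 2-fold and a solid line where both are equal. The responses have a Pearson r of 0.483 across 19743 genes, with wide scatter about the solid line and with some genes at the upper left, lower in KU50 and higher in Xinxuan048 under drought.

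Across all kept genes, the responses of the cultivars resembled each other in part. Genes at least 2-fold higher under drought in both cultivars numbered 918, where lists of these sizes drawn independently would share 231. Genes at least 2-fold lower in both numbered 287, against 28.6 for independent lists. With TMM scaling the numbers were 409 higher, against 62.3, and 604 lower, against 96.4. The correlation of the 2 responses across genes was 0.483 (Pearson) and 0.550 (Spearman), a description of these 4 libraries without a p-value. The likeness was limited. Across genes, the log2 difference of the responses had an SD of 0.761, against 0.817 for the response in KU50 and 0.656 in Xinxuan048.

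The most abundant transcripts of the leaf were lower under drought in both cultivars, while genes of low and middle abundance were higher in the FPKM as deposited. Of the 54 genes with a mean of at least 1000 FPKM, 44 were lower under drought in both cultivars and 6 were higher in both. Their median log2 ratio was -0.67 in KU50 and -0.99 in Xinxuan048. Together with the 169 genes between 300 and 1000 FPKM, they held 38.9% of all FPKM in KU50 control and 28.3% in KU50 drought. In Xinxuan048 the shares were 41.4% and 32.2%. The 32.2% includes MANES_05G208300 with 21591 FPKM and MANES_13G124700 with 18202, short loci chosen after their values were seen. In Xinxuan048 control these loci had 1217 and 608 FPKM, so they make the fall in Xinxuan048 smaller. Loci under 250 bases held 7.07% of all FPKM in Xinxuan048 drought and 0.621% in Xinxuan048 control. The 169 genes between 300 and 1000 FPKM had medians of -0.26 and -0.47. The 6327 genes between 3 and 10 FPKM had medians of 0.38 in KU50 and 0.46 in Xinxuan048. TMM scaling lowered every class, to -1.01 and -1.38 for the 54 most abundant genes and to 0.08 and 0.13 between 3 and 10 FPKM. The 6387 genes between 10 and 30 FPKM, the largest class, went from medians of 0.32 and 0.37 as deposited to 0 and 0.01 under TMM. With the same scaling, the genes between 30 and 100 FPKM turned from medians of 0.17 and 0.19 to -0.16 and -0.19. The class limits were chosen after the values were seen.

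**Figure D2:**
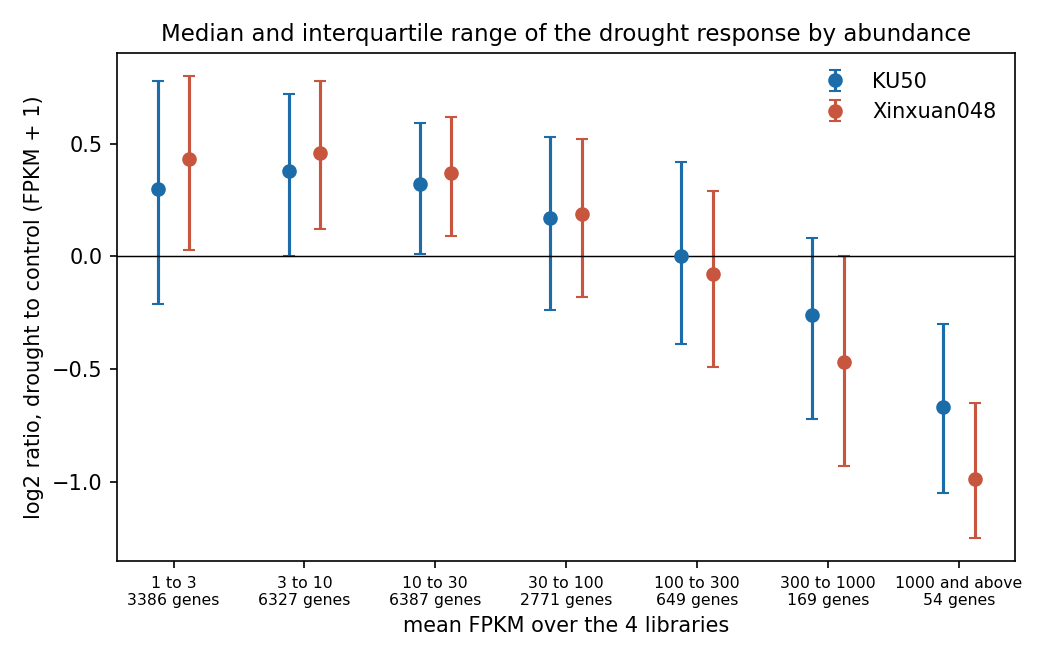
Points give the median log2 ratio of drought to control on log2(FPKM + 1), and bars the interquartile range over genes, for 7 classes of mean FPKM over the 4 libraries. The medians lie between 0.30 and 0.46 below 30 FPKM in both cultivars and at -0.67 and -0.99 for the genes of at least 1000 FPKM; TMM scaling lowers all of them.

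Within KU50, the highest log2 ratios of drought to control, on the scale of log2(FPKM + 1), belonged to 2 genes of chromosomes 1 and 3. MANES_01G042200, on chromosome 1 from 6892756 to 6893838, had 1.15 FPKM in control and 255 in drought, a log2 ratio of 6.90. MANES_03G197100, on chromosome 3 from 27961109 to 27962074, had 1.33 and 241 FPKM, a log2 ratio of 6.70. The lowest ratio was that of MANES_08G054400, on chromosome 8 from 5483137 to 5484517, with 366 FPKM in control and 1.75 in drought, a log2 ratio of -7.06. MANES_15G008400, on chromosome 15 from 792220 to 793130, had 101 FPKM in control and was unlisted in drought. In total 2173 genes were at least 2-fold higher and 1119 at least 2-fold lower. The median of all genes was 0.30 on the log2 scale, and relative to that median 1112 were at least 2-fold higher and 1741 at least 2-fold lower. Among genes at least 2-fold apart, the share that was higher was 66.0% as deposited and 70.8% with totals scaled to a common value. It was 47.1% with upper-quartile scaling and 40.9% with TMM.

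In Xinxuan048 the highest ratio under drought was that of MANES_09G025200, at 6.25 on the log2 scale. The next, MANES_14G009700, spans 166 bases of chromosome 14 from 948222 to 948387, where few fragments can make a high FPKM. It was unlisted in control and had 60.2 FPKM in drought. At the lower end stood MANES_13G057200, a locus of 150 bases on chromosome 13 from 6197030 to 6197179. It had 60.2 FPKM in control, the value assumed to be the worth of 1 fragment, and was unlisted in drought. MANES_03G039900 followed at a log2 ratio of -3.98. In total 2102 genes were at least 2-fold higher and 504 at least 2-fold lower under drought. The median was 0.37, and relative to it 868 were at least 2-fold higher and 1189 at least 2-fold lower. Among genes at least 2-fold apart, the share that was higher was 80.7% as deposited and 83.8% with totals scaled to a common value. It was 56.4% with upper-quartile scaling and 48.3% with TMM.

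Between the cultivars, some genes were high in one and far lower in the other under both conditions. MANES_14G147100, on chromosome 14 from 13987331 to 13988170, had 433 FPKM in KU50 control and 207 in KU50 drought. It was unlisted in Xinxuan048 control and had 0.397 FPKM in Xinxuan048 drought. MANES_16G037000, on chromosome 16 from 4290429 to 4291962, had 164 and 42.6 FPKM in Xinxuan048, against 2.64 and 0.234 in KU50, control before drought. With a limit of 5 FPKM in both libraries of one cultivar and less than 0.5 in both of the other, 25 genes were high in KU50 and 6 in Xinxuan048. Genes at least 2-fold apart in both conditions numbered 311 higher in KU50 and 165 higher in Xinxuan048. Under TMM scaling these numbers were 244 and 213.

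In control leaves, 476 genes were at least 2-fold higher and 1374 at least 2-fold lower in Xinxuan048 than in KU50. MANES_01G042200 had 161 FPKM in Xinxuan048 and 1.15 in KU50, a log2 ratio of 6.24. MANES_08G054400 had 0.995 FPKM in Xinxuan048 and 366 in KU50, a log2 ratio of -7.53. The median of all genes was -0.13. Relative to it 628 were at least 2-fold higher and 1082 at least 2-fold lower. The share that was higher, among genes at least 2-fold apart, went from 25.7% as deposited to 35.7% under TMM.

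Under drought, 608 genes were higher and 827 lower by the same threshold, with a median of -0.08. Of the genes past that threshold, 42.4% were higher as deposited and 51.5% under TMM. MANES_11G093200, 150 bases on chromosome 11 from 14403705 to 14403854, had 381 FPKM, the worth of 7 fragments, and was unlisted in KU50. MANES_S072600, 362 bases on an unplaced sequence, had 54.5 FPKM, equal to the worth of 1 fragment at 150 bases, and was also unlisted in KU50 drought. MANES_14G147100 and the short locus MANES_13G057200, with 93.6 FPKM in KU50 and unlisted in Xinxuan048, stood at the other end.

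No gene passed the limma test for a cultivar effect shared by both conditions (0 of 19743 at an adjusted p of 0.05). The smallest adjusted p was 0.0955, and 2881 genes passed at an unadjusted p of 0.05.

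The cultivars differed most in their drought response at genes that were high in KU50 control and in Xinxuan048 drought. MANES_07G050400, on chromosome 7 from 5233947 to 5234589, had 92.2 FPKM in KU50 control and 0.0831 in KU50 drought. In Xinxuan048 it was unlisted in control and had 55.1 FPKM in drought. MANES_15G008400 had 101 FPKM in KU50 control and was unlisted in KU50 drought, and had 0.336 and 51.5 FPKM in Xinxuan048. At the other end stood 2 genes that were low in KU50 control and higher in the other 3 libraries. MANES_01G042200 had a log2 ratio of 6.90 in KU50 and of -1.28 in Xinxuan048. MANES_10G020600, on chromosome 10 from 1575378 to 1576431, had a log2 ratio of 5.05 in KU50 and of -1.06 in Xinxuan048. By a difference of at least 1 on the log2 scale, the response was higher in Xinxuan048 at 1217 genes and lower at 685. These differences have no test, since each response rests on 1 pair of libraries.

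**Figure D3:**
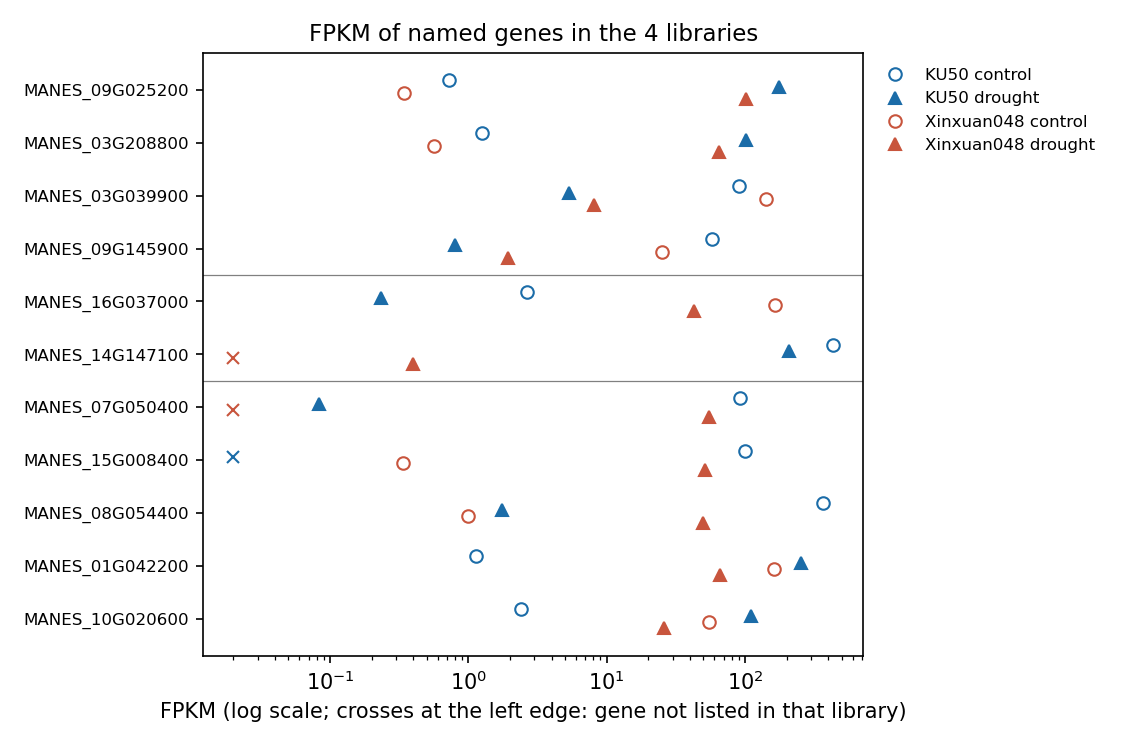
FPKM, on a log axis, of 11 named genes in the 4 libraries; open circles are control, filled triangles drought, and crosses at the left edge mark a gene unlisted in that library. The upper 4 genes move alike in both cultivars, the middle 2 differ by cultivar (433 and 207 FPKM in KU50 for MANES_14G147100), and the lower 5 move in opposite directions, such as MANES_08G054400 with 366 and 1.75 FPKM in KU50 and 0.995 and 49.6 in Xinxuan048.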

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

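The tests of locus span, of short loci, of an added source of RNA, of a common drought response and of swapped labels were chosen after the results were seen. Those of abundant genes and of low values were planned before.

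Opposite drought responses of the cultivars drew attention, and none of these differences was tested between groups. Under drought, 146 genes were at least 2-fold lower in KU50 and at least 2-fold higher in Xinxuan048, where independent lists of these sizes would share 119. The reverse held for 21 genes, against 55.5 for independent lists. MANES_08G054400 differed by 11.73 between the cultivars' log2 ratios, Xinxuan048 minus KU50, MANES_01G042200 by -8.18 and MANES_10G020600 by -6.11. MANES_15G008400, with 101 FPKM in KU50 control, and MANES_07G050400, with 92.2 there, were also lower under drought in KU50 and higher in Xinxuan048. So was MANES_11G093200, whose 51.6 FPKM in KU50 control was the worth of 1 fragment.

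The 146 genes had median values of 8.44 FPKM in KU50 control, 0.722 in KU50 drought, 0.442 in Xinxuan048 control and 4.19 in Xinxuan048 drought. Control and drought labels swapped in 1 cultivar would make the responses run against each other across genes, but Pearson's r was 0.483. Counting noise at low values as the whole cause would remove the genes from higher abundance. Among genes of at least 10 FPKM and 500 bases they were 0.439 times as frequent as among all kept genes (95% interval 0.30 to 0.62, from an exact binomial interval). That argues against noise as the whole cause, but only 32 of the 146 genes lie in that set. For the others, counting noise stays open. A difference between the cultivars in their response remains possible as a hypothesis. So does any difference between the libraries that is unrelated to drought, since with 1 library per group the 2 were not separated.

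Most genes were higher in both drought libraries as deposited, with log2 medians of 0.30 and 0.37, against 0.0771 and 0.112 with upper-quartile scaling and -6.71e-05 and 0.0323 with TMM, which centres the ratios. Scaling to a common total went the other way, with medians of 0.37 in KU50 and 0.416 in Xinxuan048. Had abundant genes taken up the difference, removing those of at least 300 FPKM and rescaling would bring the medians below 0.1. They came to 0.154 in KU50, between the bounds of 0.1 and 0.2 set beforehand, and to 0.222 in Xinxuan048, above both, so this stays open. A bias by locus span as the whole cause is argued against by medians of 0.234 and 0.330 in the shortest 25% of loci between 3 and 30 FPKM, although the longest 25% had 0.40 and 0.47. Locus span is not the transcript length by which FPKM are scaled, so a bias by transcript length was not tested. A true increase of most transcripts was not tested, because FPKM carry no measure of total RNA.

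In Xinxuan048 drought, 25 genes stood at least 4-fold above each other library, 19 of them under 500 bases; the like counts were 62 in KU50 control, 83 in KU50 drought and 8 in Xinxuan048 control, with 13, 13 and 7 under 500 bases. By the worth of a fragment at the shortest loci, a lower bound for longer ones, 6 hold at least 10 fragments, and counting noise at short loci stays open for the 15 others under 500 bases. MANES_05G208300, with 21591 FPKM, and MANES_13G124700, with 18202, chosen after their values were seen, hold at least 396 and 334 fragments, too many for that. The log2 ratios of the 6 genes over the highest other library had an SD of 0.671 (95% interval 0.419 to 1.65), which does not settle whether 1 source of RNA was added. A drought response common to both cultivars also stays open: the median log2 ratio in KU50 was 0, but 8 genes were unlisted in both KU50 libraries, the choice required 4-fold less in KU50 drought, and 1 gene, MANES_03G197100, had 6.70 in KU50.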

How the results depend on the processing

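The restrictions to genes listed in all 4 libraries and to loci of at least 500 bases, and the removal of abundant genes, were chosen after the data were seen. Comparisons within a cultivar or a condition have 1 library per group, and the additive fit has 1 residual degree of freedom, so leaving out any library leaves no error to test with. The fixed gene lists could not be run for want of descriptions. Where a value moved, the cause was not tested, except that a higher threshold or a stricter filter leaves fewer genes to count.

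The count of genes with a drought effect shared by both cultivars, 9 in the main analysis, depended most on the settings. It was 0 without a filter and 0 without the variance trend, 52 with totals scaled to a common value, 72 for genes listed in all 4 libraries and 88 for loci of at least 500 bases. It was 282 with upper-quartile scaling, 378 with TMM, 750 with a filter at a mean of 5 FPKM and 5336 at an adjusted p of 0.10. It was 8, 9 and 8 with pseudocounts of 0.1 and 0.5 and with abundant genes removed. Without the cultivar term it was 10, all of them higher under drought, so MANES_03G039900 did not pass there. The cultivar effect, 0 genes in the main analysis, had 1 gene with totals scaled to a common value, 1 without the condition term, 14 at an adjusted p of 0.10 and 0 under its other 10 alternatives.

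The counts of genes at least 2-fold apart kept within 1.5 times of the main count under the other scalings, which moved their split. With a pseudocount of 0.1, Xinxuan048 under drought had 4196 genes, the cultivars under control 2932 and the difference of responses 2894, against 2606, 1850 and 1902. With the filter at 5 FPKM, the counts were 1973 for KU50 under drought, 1596 for Xinxuan048 under drought, 1006 and 733 between cultivars under control and drought, and 945 for the difference of responses. At 4-fold they were 648, 297, 432, 332 and 518 in the same order.

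The correlation of the 2 responses was positive under each alternative. It was 0.362 and 0.445 with pseudocounts of 0.1 and 0.5, 0.455 without a filter, 0.456 with totals scaled to a common value and 0.564 with the filter at 5 FPKM. It was 0.550 by Spearman's method, 0.538 for genes listed in all 4 libraries and 0.510 for loci of at least 500 bases. Depth limits the values of loci near the shortest length, where 1 fragment is worth 51.6 FPKM in KU50 control.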

Other observations

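The 311 genes higher in KU50 in both conditions formed 20 neighbouring pairs along the genome, where 10000 random placements gave a median of 5 and at most 14. For the 165 genes higher in Xinxuan048 in both conditions there were 15 pairs, against a median of 1 and at most 7. The longest such run held 4 genes on chromosome 1 from 1830338 to 1891372, with median log2 ratios of Xinxuan048 to KU50 of 3.92 in control and 1.86 in drought. Its last members, MANES_01G0106002 and MANES_01G0106001, named after their values were seen, have tags that may be parts of a single tag. If so, the run holds fewer genes and the 15 pairs include 1 within a gene. This was not examined. Genes higher under drought in both cultivars formed 68 pairs, against a median of 42 and at most 68 in random placements. Genes lower in both formed 10 pairs, against a median of 4 and at most 15.

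The 146 genes lower in KU50 and higher in Xinxuan048 under drought formed 8 pairs, against a median of 1 and at most 6. Their longest run held 4 genes on chromosome 12 from 4136922 to 4258804, with median log2 ratios of drought to control of -3.58 in KU50 and 2.21 in Xinxuan048. Sharing of reads between near-identical neighbouring copies was not examined.

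In these 4 libraries, a larger share of genes on unplaced sequences than on the 18 chromosomes differed between the cultivars. Of 474 such genes, 30 were at least 2-fold apart in the same direction in both conditions, or 6.33% (95% exact binomial interval 4.31 to 8.91). On the chromosomes the share was 2.31% (2.11 to 2.54). Among loci of at least 500 bases the shares were 5.18% and 2.08%. Chromosome 7 had the highest share among the chromosomes, 4.91% of 774 genes. The intervals treat genes as independent, which the neighbouring pairs above speak against, so they are too narrow, and they hold no error between plants. For the drought response the shares were 5.27% on unplaced sequences and 6.12% on chromosomes.

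The 4 libraries can be divided into pairs in 3 ways. With at least 5 FPKM in both libraries of a pair and under 0.5 in both others, 11 genes were high in the drought libraries and 0 in the control libraries. Another 25 were high in KU50 and 6 in Xinxuan048. The crossed division gave 8 genes high in KU50 control and Xinxuan048 drought, and 0 high in the other pair.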
